A study of Mus musculus with 18 samples.

How the data were processed

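The deposited data were 18 Agilent mouse 44k arrays, 1-colour hybridizations of RNA from sorted cells, 1 array per sample. Per the labels, cells were sorted by fluorescence from neonatal brain (OPC, 3 arrays), from 2-month-old brain (OPC, 4; OL, 4), and as OPCs from 2-month-old mice after 5 weeks of cuprizone (4) or under control conditions (3). RNA was extracted with a column kit, amplified with the Agilent low input kit and labelled with Cy3. The sort markers, the number of animals per sample, the sexes and the age of neonatal mice in days were not given in the sources used here. The array was the unit of analysis, and groups were taken from the sample titles.

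The deposited intensity values were median pixel brightness of each spot at 532 nm and its local background, as written by the scanner software Mapix 5.0.0 per the file headers, with no normalization. The deposited percent values gave the share of saturated pixels of a spot, per the file headers. Values of the second channel, 635 nm, were 0 on the arrays of set 1. The authors' log2 values in the deposited series table had array medians between 8.50 and 8.55, blanks for 0.905% to 28.2% of probes, and rank correlations of 0.998 or more with spot signal minus background. How the authors normalized these log2 values and chose the blanks was not given in the sources used here. They were used as an alternative only.

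The plan written before the data were examined named signal columns of another scanner program, which the files did not hold. Median spot signal and local background took their place. Quantile normalization also replaced scaling to the 75th percentile as the main setting, and the latter was kept as an alternative. Background was corrected with normexp (offset 50) in limma 3.58.1 under R 4.3.3 with the package data.table (version 1.17.8), and values were taken to log2. Spots marked bad were left out, and arrays of a comparison were quantile normalized together. Of 45220 spots per array 2200 were controls or ignored, and the others held 39429 probes, of which spots of a probe were averaged. A single gene was assigned to 30625 probes, none to 8804 and several to 0, with 20 symbols updated, 30331 matched by Entrez number, 30 by accession and 264 kept as given. Each of 21885 genes was represented by its probe with the highest mean over the 18 arrays. Where other probes of a gene are mentioned, they were not used for the test.

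A probe was well above background where signal minus background exceeded the median of 153 negative control spots by 2.6 robust SDs, and saturated where over 50% of its pixels were. Genes well above background on all arrays of at least 1 group of the fit were tested. Between 41.9% and 61.3% of probes passed on an array of set 1 and between 32.6% and 44.5% on an array of set 2. Where 1 group had no array above background, a change was given as a lower bound, at least so many fold, against the detection threshold. Where 1 group was saturated on every array the fold was also a lower bound. No fold was given where both groups were saturated or both below background.

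Neonatal OPC, adult OPC and adult OL entered a single limma fit. Cuprizone and control OPC entered another fit, and control and adult OPC a further one. Coefficients were moderated with eBayes and p adjusted by Benjamini-Hochberg over the genes tested, and a gene was called at an adjusted p under 0.05. All adjusted p of genes came from limma, and the ± beside a log2 change is its SE. The groups had 3 or 4 arrays. In data simulated with the same spread, 29.9% to 58.2% of genes changed 2-fold and 81.8% to 98.5% of genes changed 4-fold were called, so small changes were often missed. Between 1 and 7 unchanged genes were called per comparison.

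The 26 gene lists were fixed before the data were examined and held 559 members, 535 of them on the array. Lists with at least 3 tested members were tested with camera of limma (preset correlation 0.01), with camera with an estimated correlation and with fry, each adjusted by Benjamini-Hochberg over the lists of a comparison. Members called were also counted with p adjusted over the list alone. In simulated data with no change, between 0 and 1 lists were called per comparison. Genes were simulated independently of each other, so this does not measure list calls that arise from correlated members. The lists were cell type markers (OPC, committed and newly formed oligodendrocyte, mature oligodendrocyte, astrocyte, neuron, microglia and macrophage, endothelial, pericyte and perivascular fibroblast, lymphocyte and granulocyte, ependymal and choroid plexus, erythroid), cell cycle, cholesterol biosynthesis, neural progenitor factors and oligodendrocyte differentiation factors. The others were cytokine ligands, cytokine receptors and innate sensors, interferon response, antigen presentation, adhesion, guidance and migration, growth factor signalling, neurotransmitter receptors and channels, stress response, immediate early genes, metallothionein and oxidative stress, and the respiratory chain.

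Genes named in the text were chosen by a rule written before the data were examined. It took the 6 genes per direction with the largest change among called genes above background on every array of both groups and with the groups not overlapping, and the 3 per direction with the largest lower bound. It added up to 3 called members of each list, with Mbp, Mki67, Pdgfra, Cspg4, Ccl2 and Il1b in any case. For adult OL minus neonatal OPC it took 3 genes per direction, and for changes shared by the cuprizone and neonatal comparisons 5 per direction. Members named where 5 or fewer of a list were called, members saturated in both groups, and the genes of control minus adult OPC were named after their values were seen. Control minus adult OPC otherwise had counts and lists only.

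Scores per array were the mean of genes called at least 2-fold higher minus the mean of genes called at least 2-fold lower in the first set, taken in the second. Of these genes, only those that passed the filter of set 2 entered. Score differences were tested with exact two-sided permutation tests, and the distance of adult OPC arrays with an exact sign-flip permutation test. The overlap of called genes was set against n1 x n2 / N, the number for independent lists. Slide was used as a block, and comparisons were repeated within single slides. Scan day was the same for all arrays of a set and differed between the sets, so it could not serve as a block within a set. Alternatives covered the authors' values, scaling to the 75th percentile, plain subtraction of background, no filter on dim probes, a filter on every array, other ways to join probes of a gene, trend and robust eBayes, array weights, replicate number as a block, the groups in the fit, and leaving out each array. Plain subtraction, slide as a block for the lists and 75th percentile scaling for the lists were chosen after seeing the data. Plots were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.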

Results

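Gene expression was measured in cells of the oligodendrocyte lineage sorted from mouse brain, on 18 arrays, 1 array per RNA sample. Oligodendrocytes (OLs) wrap axons in myelin, and oligodendrocyte precursor cells (OPCs) divide, migrate and differentiate into them. The groups were OPCs of newborn mice (neonatal OPC, n = 3), OPCs of 2-month-old mice (adult OPC, n = 4), OLs of 2-month-old mice (adult OL, n = 4), OPCs of 2-month-old mice given cuprizone for 5 weeks (cuprizone OPC, n = 4) and OPCs of their control mice (control OPC, n = 3). Cuprizone is a copper chelator that, when fed to mice, kills oligodendrocytes and strips axons of myelin. The labels call the replicates independent but do not say how animals were pooled. The first 3 groups (set 1) were scanned on slides 1 to 3 and the other 2 (set 2) on slides 4 and 5 with another scanner. Changes were computed within a set, except between control and adult OPCs. Between 41.9% and 61.3% of probes were well above background on an array of set 1, and between 32.6% and 44.5% on an array of set 2. From 49 to 860 probes per array were saturated. The number of arrays per group limited the precision of every value.

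Adult OPCs resembled adult OLs far more than neonatal OPCs. The mean correlation between arrays, across 11920 genes that are not independent replicates, was 0.961 between adult OPCs and adult OLs and 0.758 between adult and neonatal OPCs. It was 0.967 among the adult OPC arrays themselves. Across 11955 genes, the root mean square log2 difference from an adult OPC array to the neonatal mean was 1.36 ± 0.06 (SD, n = 4), and to the adult OL mean 0.51 ± 0.03. The distance to neonatal OPCs was larger for 4 of 4 adult OPC arrays, by 0.85 ± 0.05 (exact two-sided sign-flip permutation test, p = 0.125, the smallest that 4 arrays can give). Across sets, so that differences between the sets enter, control OPCs correlated with neonatal OPCs at 0.716 and cuprizone OPCs at 0.799. The cuprizone arrays correlated with the control arrays at 0.906.

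The comparison of neonatal with adult OPCs addresses how the precursor profile changes with age, as far as the sorts held precursors alone. The lists of OPC markers and cell cycle genes were higher in neonatal OPCs by camera and that of mature oligodendrocyte markers lower, and of these 3 calls that of the cell cycle held with an estimated correlation. Pdgfra, the receptor through which platelet-derived growth factor drives precursor division, was 31.8-fold higher in neonatal OPCs (12.86 ± 0.35 against 7.87 ± 0.50 log2 units, SD, n = 3 and 4; limma adjusted p = 8.33e-09), with 3 of 4 adult arrays above background. Mki67, a marker of dividing cells, was 31.0-fold higher (log2 change 4.95 ± 0.50, SE as in all log2 changes here). Opalin, a glycoprotein of myelinating oligodendrocytes, was not well above background on any neonatal array and was at least 50.5-fold higher in adult OPCs. Of 12032 genes tested, 2638 were higher and 2889 lower in neonatal OPCs at an adjusted p under 0.05, of which 1938 and 1750 changed at least 2-fold. The count was 4943 in all with slide as a block, and 99.9% of the called genes kept their direction within slide 1 and within slide 3, which held both groups. For 88.5% of the called genes the arrays of the 2 groups did not overlap, which fixed their direction within a slide.

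Among genes well above background on every array of both groups, the largest rises in neonatal OPCs were those of Col3a1, a fibrillar collagen (log2 change 6.48 ± 0.26), Fabp7, a fatty acid binding protein of neural progenitors (6.27 ± 0.36), Sapcd2, a regulator of spindle orientation (6.21 ± 0.28), and Fxyd6, a regulator of the sodium pump (5.70 ± 0.35). Dpysl3, a cytoskeletal protein of growth cones and migrating cells, followed at 5.61 ± 0.27, although its other probe gave only 0.93, and Mfap2, a microfibril protein, at 5.54 ± 0.23. Among genes not well above background on any adult OPC array, Nid2, a basement membrane protein, was at least 13.8-fold higher in neonatal OPCs, Lrrc17 at least 9.0-fold and Col5a1, a collagen of fibril cores, at least 7.79-fold. Under the same limit, the largest falls were those of Ppp1r14a, an inhibitor of myosin phosphatase abundant in oligodendrocytes (-7.37 ± 0.27), Aspa, which cleaves N-acetylaspartate (-6.63 ± 0.40), Prr5l, a partner of the mTORC2 kinase complex (-6.54 ± 0.32), and Gpr37, a receptor of maturing oligodendrocytes (-6.54 ± 0.29; other probe -2.51). Galnt6, an enzyme of O-glycosylation, fell by 6.11 ± 0.34. Sez6l2 was saturated on every adult OPC array and was at least 108-fold higher there. Rftn1, a lipid raft protein, and Klk6, a secreted protease of oligodendrocytes, were not well above background on any neonatal array and were at least 34.0-fold and 23.1-fold higher in adult OPCs.

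Lineage markers followed the same order. Of 10 tested OPC markers, 9 were higher in neonatal OPCs (9 adjusted over the list alone), among them Emid1 at 5.02 ± 0.28 (other probe 1.37) and Cspg4, the NG2 proteoglycan of precursors, at 4.96 ± 0.37 (camera adjusted p = 2.86e-07; adjusted p = 0.103 with an estimated correlation). Markers of committed and newly formed oligodendrocytes rose too, 9 of 12 (9 adjusted over the list alone), including Itpr2, a calcium release channel (3.72 ± 0.27), and Bmp4, a growth factor that holds back differentiation (3.17 ± 0.38; camera adjusted p = 0.000768, and adjusted p = 0.351 with an estimated correlation). Of 24 mature oligodendrocyte markers, 22 were lower in neonatal OPCs (22 adjusted over the list alone; camera adjusted p = 1.15e-13; adjusted p = 0.0583 with an estimated correlation). Car2, a carbonic anhydrase, was saturated on every adult OPC array and at least 277-fold higher there, with 2 of 3 neonatal arrays above background. Mbp, myelin basic protein, was -2.36 ± 0.26 by its brightest probe, and its other probes ranged from -1.63 to 1.48. The median changes of these 3 lists were 3.02, 1.96 and -4.88. They were 3.12, 2.12 and -4.78 with slide as a block, 3.11, 2.36 and -4.20 within slide 1, and 3.44, 1.73 and -4.90 within slide 3.

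Cell cycle genes rose in neonatal OPCs as a group: 22 of 28 were higher and 0 lower (22 adjusted over the list alone), with Birc5, a survivin that guards chromosome segregation, at 3.79 ± 0.23 (other probes 1.03 to 1.33) and Ccnd1, cyclin D1, at 3.67 ± 0.27. It was the single list whose call held with an estimated correlation (camera adjusted p = 3.15e-11 and 0.0279; median 1.65, 1.72 with slide as a block, 1.62 and 1.57 within slides 1 and 3). Progenitor transcription factors followed with 11 of 20 higher and 1, Meis1, lower (12 adjusted over the list alone). Examples were Sox4, at 4.52 ± 0.29, Hes5, an effector of Notch signalling, at 3.96 ± 0.42, and Sox11, at 2.90 ± 0.22 with 1 of 4 adult arrays above background (camera adjusted p = 0.000251; adjusted p = 0.131 with an estimated correlation; median 1.12, 1.13 with slide as a block, 1.18 and 1.36 within slides). Among 16 oligodendrocyte differentiation factors 2 were higher and 4 lower (6 adjusted over the list alone; camera adjusted p = 0.561). Nkx6-2 and Myrf, regulators of myelin genes, were not well above background on any neonatal array and were at least 19.3-fold and 1.92-fold higher in adult OPCs.

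Growth factor, adhesion and channel genes moved both ways, mostly upward in neonatal OPCs. In growth factor signalling 12 of 20 were higher and 4 lower (16 adjusted over the list alone; camera adjusted p = 0.00500; adjusted p = 0.174 with an estimated correlation). Igfbp2, a binding protein of insulin-like growth factors, was at 5.24 ± 0.30, and Fgf1, a fibroblast growth factor, at -5.94 ± 0.35 with its other probe at -1.63. In adhesion, guidance and migration 19 of 32 were higher and 3 lower (22 adjusted over the list alone; camera adjusted p = 0.000696; adjusted p = 0.127 with an estimated correlation), with Bcan, a brain proteoglycan, at 3.77 ± 0.44 and Unc5b, a netrin receptor, at -6.10 ± 0.27. Of 23 neurotransmitter receptors and channels 15 were higher and 5 lower (20 adjusted over the list alone; camera adjusted p = 0.00272; adjusted p = 0.127 with an estimated correlation). Kcnd3, a potassium channel, was at 4.99 ± 0.29 with 3 of 4 adult arrays above background, and Kcna1, another, at -5.74 ± 0.28. The median changes of these 3 lists were 1.73, 1.12 and 1.37. With slide as a block they were 1.73, 1.21 and 1.5, within slide 1 they were 1.77, 1.28 and 1.40, and within slide 3 they were 2.15, 1.20 and 1.38.

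Markers of other cells differed between these sorted groups. All 7 tested markers of pericytes and perivascular fibroblasts were higher in neonatal OPCs (7 adjusted over the list alone), with the collagen Col1a1 at 5.10 ± 0.28 and Vtn, vitronectin, at 5.07 ± 0.46 (camera adjusted p = 2.86e-07; adjusted p = 0.103 with an estimated correlation; median 4.10, 4.00 with slide as a block, 4.17 and 4.14 within slides). They rose in the same arrays as Col3a1 and Col5a1. Which cells of the neonatal sort held these transcripts was not tested, so their rises cannot be assigned to the precursors. Of 13 astrocyte markers 7 were higher and, without adult OPC replicate 4, 1 lower (7 adjusted over the list alone), with the connexin Gjb6 at 2.43 ± 0.42 (camera adjusted p = 0.00305; adjusted p = 0.286 with an estimated correlation; median 1.22, 1.08 with slide as a block, 1.14 and 1.31 within slides). Among 14 microglia and macrophage markers 1, Tmem119, was higher (1 adjusted over the list alone) at 2.29 ± 0.33, with 3 of 4 adult arrays above background (camera adjusted p = 0.510). Between 1 and 5 of these markers were higher when single arrays were left out. Markers of neurons (2 of 6 higher, 1 lower), endothelium (2 of 8 higher), lymphocytes and granulocytes (1 of 5 lower), ependyma and choroid plexus (3 of 5 higher, 2 lower) and erythroid cells (0 of 4) had camera adjusted p of 0.561, 0.549, 0.604, 0.682 and 0.682. Adjusted over the list alone, these lists held 3, 2, 1, 5 and 0 calls.

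Immediate early genes, which tissue dissociation also induces, were higher in neonatal OPCs for 10 of 16 (13 adjusted over the list alone), with Egr1 at 2.53 ± 0.62 and Socs3, a brake on cytokine signalling, at 2.68 ± 0.51 (camera adjusted p = 0.00462; adjusted p = 0.639 with an estimated correlation; median 1.41, 1.21 with slide as a block, 1.09 and 1.09 within slides). Without neonatal replicate 3 the call was lost (camera adjusted p = 0.0742), with 6 higher, 2 lower and a median of 0.89, and without adult OPC replicate 2 a single gene was lower. Cytokine and chemokine ligands went both ways, with 7 of 13 higher and 4 lower (11 adjusted over the list alone; camera adjusted p = 0.330). Cxcl12, a chemokine that guides precursors, was at 4.17 ± 0.43, and Il33, an alarmin of the interleukin family, at -6.97 ± 0.52 with 2 of 3 neonatal arrays above background. Cytokine receptors and innate sensors had 6 of 18 higher and 3 lower (9 adjusted over the list alone; camera adjusted p = 0.549), with the tumour necrosis factor receptor Tnfrsf1a at 3.62 ± 0.21. Without single arrays 3 to 6 of these were higher and 3 to 4 lower. The integrated and endoplasmic reticulum stress list split into 8 of 21 higher and 6 lower (14 adjusted over the list alone; camera adjusted p = 0.503), with Nupr1, a stress-induced nuclear protein, at 3.47 ± 0.40, Asns, asparagine synthetase, at 2.87 ± 0.22 and Phgdh, of serine synthesis, at -3.30 ± 0.40. Cholesterol synthesis had 1 of 19 higher and 5 lower (5 adjusted over the list alone; camera adjusted p = 0.224), with Dhcr7, of its last steps, at -1.71 ± 0.28. Interferon response (3 of 17 higher, 3 lower), antigen presentation (3 of 11 higher, 1 lower), metallothionein and oxidative stress (5 of 18 higher, 5 lower) and respiratory chain (0 of 29 higher, 1 lower) had camera adjusted p of 0.604, 0.712, 0.961 and 0.682. Adjusted over the list alone they held 6, 4, 11 and 1 calls. When single arrays were left out, 2 to 9 interferon members were higher and 1 to 2 lower. For antigen presentation, 1 to 4 were then higher and 0 to 3 lower. Xaf1, a proapoptotic interferon target, was not well above background on any neonatal array and at least 14.7-fold higher in adult OPCs.

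**Figure D1:**
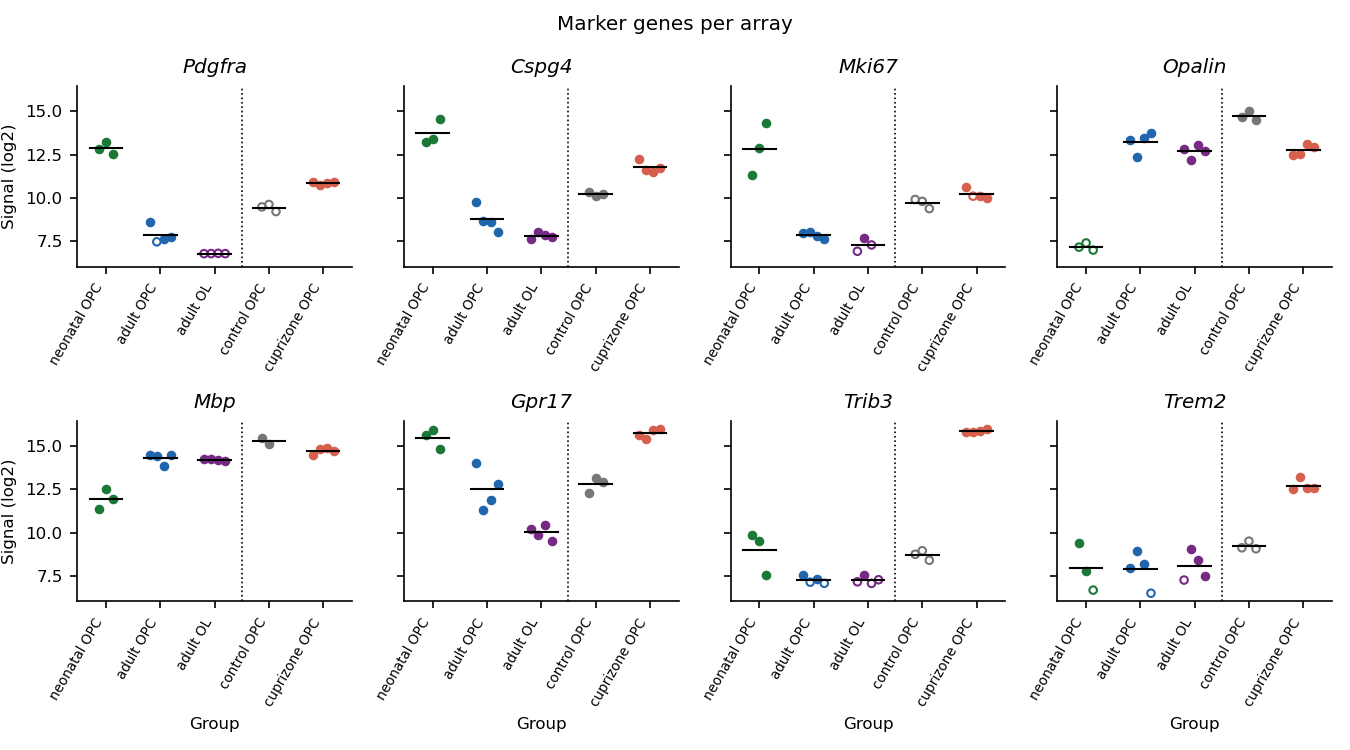
Normalized log2 signal (y axis, log2 units) of 8 genes on each array, by group (x axis). Points are arrays, horizontal bars are group means, and open points lie below the detection threshold. Sets 1 and 2, parted by a dotted line, were normalized separately. Pdgfra averaged 12.86 in neonatal and 7.87 in adult OPCs, and Trib3 15.88 in cuprizone and 8.71 in control OPCs.

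The comparison of adult OLs with adult OPCs asks how far the sorted adult precursors differed from their mature progeny. Few genes did. The list of pericyte and perivascular fibroblast markers was lower in OLs, while the mature oligodendrocyte markers, including Mbp (log2 change -0.11 ± 0.24, adjusted p = 1), did not pass the test. Adamts4, a protease that cleaves proteoglycans, was 28.7-fold higher in adult OPCs (15.24 ± 0.69 against 10.39 ± 0.44 log2 units, SD, n = 4 and 4; adjusted p = 7.23e-06), although its other probe gave 0.88 in favour of OLs. Bmp4 was 7.58-fold higher in adult OPCs, and Gpr17, a receptor of committed precursors, 5.61-fold. Of 12032 genes, 40 were higher and 160 lower in OLs, of which 33 and 149 changed at least 2-fold. The count of 200 fell to 119 with slide as a block and lay between 112 and 182 when single arrays were left out. For all 200 the arrays of the 2 groups did not overlap, so their direction within slides 1, 2 and 3 was fixed and is no check on slide. In all, 904 genes had an unadjusted p under 0.05.

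Among the other large falls in OLs were Dusp26, a phosphatase (-4.49 ± 0.23), Igfbp6 and Igfbp5, which bind insulin-like growth factors (-3.12 ± 0.33 and -2.67 ± 0.35), and the collagen Col1a2 (-3.53 ± 0.27). Dcn, the proteoglycan decorin, Col6a1, a collagen, and Slco4a1, an organic anion transporter, were not well above background on any OL array. They were at least 15.9-fold, 6.81-fold and 5.21-fold higher in adult OPCs, and the call for Slco4a1 was lost with slide as a block and without adult OPC replicate 3 or OL replicates 1, 3 or 4. Among genes well above background on every array, the largest rises in OLs were those of Fcho1, an endocytic protein (5.51 ± 0.87, with adult OPC arrays spread by an SD of 2.45), Large2, a glycosyltransferase of dystroglycan (4.71 ± 0.30), and Scrg1 (3.07 ± 0.52). Plin4, a lipid droplet protein, rose by 2.55 ± 0.37, Pxdn, a matrix peroxidase, by 2.10 ± 0.34 and Ocel1 by 1.97 ± 0.27, with its other probe at -0.57. Rufy4, Npy, which encodes neuropeptide Y, and Tescl were not well above background on any adult OPC array and were at least 7.41-fold, 4.24-fold and 1.92-fold higher in OLs.

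Of the 10 OPC markers 1, Pdgfra, was called lower in OLs (4 adjusted over the list alone; camera adjusted p = 0.000670; adjusted p = 0.383 with an estimated correlation). It was not well above background on any OL array, was at least 1.42-fold higher in adult OPCs (adjusted p = 0.0393), and lost its call with slide as a block and without any 1 of the arrays other than adult OPC replicate 2. Cspg4 was at -0.95 ± 0.34 (adjusted p = 0.344) and Mki67, above background on 1 of the 3 OL arrays that measured it, at -0.58 ± 0.50 (adjusted p = 1). Among 12 markers of committed and newly formed oligodendrocytes 2, Bmp4 and Gpr17, were lower (4 adjusted over the list alone; camera adjusted p = 6.06e-05; adjusted p = 0.383 with an estimated correlation). Of 24 mature oligodendrocyte markers 7 were saturated in both groups and 1, Ninj2, an adhesion protein, was lower in OLs at -1.19 ± 0.23 (1 adjusted over the list alone; camera adjusted p = 0.851), a call that ended with slide as a block (adjusted p = 0.0503) and without adult OPC replicates 3 or 4 or OL replicates 1, 3 or 4. Without OL replicate 4 the call of Gpr17 was lost too. The 15 markers measured in both groups had a median change of -0.07. Median changes of the 3 lists were -0.44, -0.48 and 0.06. With slide as a block they were -0.46, -0.43 and 0.12. Within slides 1, 2 and 3 the OPC list gave -0.75, -0.60 and -0.16, the committed list -0.53, -0.20 and -0.41, and the mature list -0.08, -0.09 and 0.45.

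Pericyte and perivascular fibroblast markers gave the strongest shift between the adult groups: 5 of 7 were lower in OLs and 0 higher (6 adjusted over the list alone), Dcn, Col1a2 and Col1a1 (-2.90 ± 0.26, with 3 of 4 OL arrays above background) among them. The call held with an estimated correlation (camera adjusted p = 1.09e-19 and 0.0210). The median was -2.28, with -2.25 with slide as a block and -2.28, -2.39 and -1.99 within slides 1, 2 and 3. In adhesion, guidance and migration 3 of 32 were lower and 1 higher (11 adjusted over the list alone), with Fn1, fibronectin, at -3.28 ± 0.49 with 2 of 4 OL arrays above background and Cd44, a hyaluronan receptor, at 1.65 ± 0.33 (camera adjusted p = 0.000752; adjusted p = 0.291 with an estimated correlation; median -0.25, -0.22 with slide as a block, -0.36, -0.24 and -0.12 within slides). Progenitor transcription factors had 3 of 20 lower (4 adjusted over the list alone; camera adjusted p = 0.00799; adjusted p = 0.383 with an estimated correlation; median -0.24, -0.21 with slide as a block, -0.50, -0.35 and 0.01 within slides). These were Sox4 (-1.29 ± 0.27), Id1 (-1.38 ± 0.27) and Id3 (-1.05 ± 0.24), inhibitors of differentiation, and slide as a block ended the calls of Id1 and Id3. The list call was lost without adult OPC replicate 2 (adjusted p = 0.104, 1 lower) and OL replicate 4 (adjusted p = 0.0579, 0 lower). Members lower numbered 0 without adult OPC replicates 1 or 3 or OL replicate 1, and 1 without OL replicate 3. Cd44 lost its call without adult OPC replicates 1, 2 or 3 or OL replicate 1. The immediate early list shifted down with 0 of 16 members called (0 adjusted over the list alone; camera adjusted p = 0.00254; adjusted p = 0.522 with an estimated correlation; median -0.45, -0.48 with slide as a block, -0.83, -0.34 and -0.39 within slides, -0.72 without OL replicate 2).

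The remaining lists did not pass in adult OLs against adult OPCs with all arrays. Growth factor signalling had 2 of 20 lower (4 adjusted over the list alone), cell cycle had 1 of 28 lower, the replication licensing factor Mcm6 at -1.28 ± 0.19 (1 adjusted over the list alone), and astrocyte markers had 1 of 13 higher, Ndrg2 at 1.76 ± 0.28, and 1 lower, Gjb6 at -2.29 ± 0.39 (2 adjusted over the list alone). The camera adjusted p of these 3 lists were 0.107, 0.194 and 0.475. Neuron markers had 1 of 6 higher, Npy (2 adjusted over the list alone; camera adjusted p = 0.107, and 0.0470 with slide as a block). Endothelial, microglia, lymphocyte, ependymal and erythroid markers, cholesterol synthesis, oligodendrocyte factors, cytokine ligands, receptors, interferon response, antigen presentation, channels, stress response, oxidative stress and respiratory chain had 0 members called. Their camera adjusted p ran from 0.170 to 0.851, and the ligands and receptors held 1 call each adjusted over the list alone. Leaving out 1 array brought some lists past the threshold, at adjusted p from 0.0152 to 0.0449. These were erythroid without adult OPC replicate 2, neuron and microglia without OL replicate 1, lymphocyte and growth factor without OL replicate 2, and cholesterol synthesis and antigen presentation without OL replicate 4. Without adult OPC replicate 4 they were cholesterol synthesis, cytokine ligands, antigen presentation, growth factor and channels.

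Adult OLs were also compared with neonatal OPCs, on the same 3 neonatal arrays as adult OPCs were. Of 12032 genes 3095 were higher and 2849 lower in OLs, 5081 in all with slide as a block. Within slides 1 and 3, 99.2% and 99.9% of the called genes kept their direction, which was fixed for the 90.6% whose groups did not overlap. Ppp1r14a and Sez6l2 were saturated on every OL array and at least 187-fold and 121-fold higher than in neonatal OPCs, and Gpr37 was at 6.81 ± 0.29. Col1a2 was at -7.77 ± 0.29, Pcolce, an enhancer of collagen processing, at -6.24 ± 0.30 and Rcn3, a calcium binding protein of the secretory pathway, at -6.20 ± 0.25. Mature oligodendrocyte markers were higher in OLs for 22 of 24 (22 adjusted over the list alone; camera adjusted p = 1.14e-12), and OPC markers lower for 9 of 10 (9 adjusted over the list alone; camera adjusted p = 3.41e-07). With an estimated correlation, the adjusted p of these lists were 0.0717 and 0.0766. Their medians were 4.76 and -3.63, with 4.85 and -3.68 with slide as a block, 4.24 and -4.27 within slide 1 and 4.83 and -3.64 within slide 3. Cell cycle genes were lower for 23 of 28 (23 adjusted over the list alone; camera adjusted p = 1.58e-10, and 0.0343 with an estimated correlation; median -1.63, -1.61 with slide as a block, -1.58 and -1.85 within slides). Pericyte and fibroblast markers were lower for 7 of 7, committed oligodendrocyte markers for 9 of 12, progenitor factors for 12 of 20 with 1 higher, and adhesion genes for 20 of 32 with 5 higher. Channels were lower for 16 of 23 with 4 higher, immediate early genes for 12 of 16 with 2 higher, growth factor genes for 12 of 20 with 3 higher and astrocyte markers for 7 of 13 with 2 higher. The camera adjusted p of these 8 lists ran from 1.98e-08 to 0.0243, and with an estimated correlation from 0.0766 to 0.480. Medians were -5.40, -2.78, -1.33, -1.39, -1.48, -1.95, -2.23 and -1.24 (for channels -0.89 over the 14 members measured in both groups), and with slide as a block -5.21, -2.81, -1.25, -1.45, -1.62, -1.77, -2.21 and -1.03. Within slide 1 they were -5.35, -3.29, -1.23, -1.50, -1.34, -1.92, -2.47 and -1.32, and within slide 3 -5.18, -2.20, -1.30, -1.46, -1.60, -1.83, -1.95 and -0.80. Adjusted over the list alone they held 7, 9, 14, 25, 20, 15, 16 and 9 calls. Members higher numbered 0 for progenitor factors without neonatal replicate 1, 2 for channels without OL replicate 2, and 1 for astrocytes without any 1 array but neonatal replicate 3. For immediate early genes they numbered 0 without neonatal replicates 1 or 2 or OL replicate 4, and 1 without OL replicates 1 or 2. The other 15 lists, cholesterol synthesis with 10 of 19 higher and 1 lower among them, had camera adjusted p of 0.0935 or more.

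The comparison of cuprizone with control OPCs asks how adult precursors change under demyelination. After cuprizone the lists of stress response genes and of committed and newly formed oligodendrocyte markers were higher and that of cholesterol synthesis lower, calls that held with an estimated correlation. Camera also called OPC, immediate early, microglia, antigen presentation and interferon lists higher and mature oligodendrocyte markers lower, calls that were lost with an estimated correlation. Trib3, a pseudokinase of the integrated stress response, was not well above background on any control array and was at least 71.2-fold higher after cuprizone (adjusted p = 7.18e-08). Cdkn1a, the cell cycle inhibitor p21, was at least 41.7-fold higher. Tagln2, an actin-bundling protein, was 34.8-fold higher (15.90 ± 0.10 against 10.78 ± 0.13 log2 units, SD, n = 4 and 3; adjusted p = 1.06e-07). Of 8902 genes tested 1284 were higher and 1277 lower after cuprizone, of which 568 and 433 changed at least 2-fold. The count was 2197 with slide as a block, and 99.96% and 100% of the called genes kept their direction within slides 4 and 5. That direction was fixed for the 97.6% of called genes whose groups did not overlap.

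Other large rises were those of Nupr1 (4.76 ± 0.26), Slc7a1, a carrier of cationic amino acids (4.23 ± 0.15), Gadd45g and Gadd45b, induced by growth arrest and DNA damage (4.02 ± 0.26 and 3.57 ± 0.16), and Marcks, a substrate of protein kinase C (3.79 ± 0.25). Moxd1, a monooxygenase, was not well above background on any control array and at least 12.7-fold higher. Among genes well above background on every array, the largest falls were those of Carns1, which makes carnosine (-3.15 ± 0.37), Ninj2 (-2.65 ± 0.30), Sgk2, a kinase (-2.62 ± 0.20), and Shtn1, a protein of axon outgrowth (-2.49 ± 0.23). Itih3, which binds hyaluronan, fell by 2.43 ± 0.25 and Adamtsl4, a microfibril protein, was at -2.30 ± 0.14. Fads6, a fatty acid desaturase, Col2a1, a collagen, and Gpr61, an orphan receptor, were not well above background on any cuprizone array and were at least 2.56-fold, 2.43-fold and 2.22-fold higher in control OPCs.

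The integrated and endoplasmic reticulum stress list had 15 of 21 members higher and 0 lower after cuprizone (17 adjusted over the list alone), among them Asns at 4.33 ± 0.27 with 2 of 3 control arrays above background. Without control replicate 2 a single member was lower. The call held with an estimated correlation (camera adjusted p = 3.55e-10 and 0.0182; median 1.38, 1.38 with slide as a block, 1.47 and 1.31 within slides 4 and 5). Immediate early genes were higher for 14 of 16 (14 adjusted over the list alone), with Socs3 at 3.11 ± 0.18, Klf4 at 3.05 ± 0.18 and Egr1 at 2.53 ± 0.14 (camera adjusted p = 1.42e-11; adjusted p = 0.0759 with an estimated correlation; median 1.53, 1.54 with slide as a block, 1.48 and 1.58 within slides). In metallothionein and oxidative stress 5 of 16 were higher and 1, the peroxidase Prdx1, lower at -1.43 ± 0.19 (6 adjusted over the list alone; camera adjusted p = 0.106). Mt2, a metal-binding metallothionein, was saturated on every cuprizone array and at least 10.3-fold higher there. The respiratory chain had 5 of 29 higher (3 adjusted over the list alone; camera adjusted p = 0.0844), with Sdhb of complex II at 0.98 ± 0.20.

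Precursor markers rose after cuprizone. Of 9 tested OPC markers 7 were higher and 1, Pcdh15, lower (8 adjusted over the list alone; camera adjusted p = 0.00107; adjusted p = 0.122 with an estimated correlation), with Cspg4 at 1.55 ± 0.19. Pdgfra was not well above background on any control array and at least 2.17-fold higher after cuprizone (adjusted p = 0.000230). Markers of committed and newly formed oligodendrocytes were higher for 7 of 12 and lower for 0 (8 adjusted over the list alone), with Gpr17 at 2.95 ± 0.23 and Itpr2 at 2.21 ± 0.16, a call that held with an estimated correlation (camera adjusted p = 1.88e-05 and 0.0382). Of 24 mature oligodendrocyte markers 13 were lower and 0 higher (14 adjusted over the list alone; camera adjusted p = 6.88e-05; adjusted p = 0.122 with an estimated correlation), and 5 were saturated in both groups. Opalin was at -1.96 ± 0.20, Anln, a cytoskeletal protein of myelin, at -1.87 ± 0.16, and Mbp, measured on 2 of 3 control arrays, at -0.57 ± 0.18, which missed the threshold (adjusted p = 0.0504) and passed it with slide as a block (adjusted p = 0.0370) and without control replicate 3. The medians of the 3 lists were 0.81, 1.47 and -0.74, the last being -1.26 over the 13 markers measured in both groups. With slide as a block they were 0.89, 1.45 and -0.71, within slide 4 they were 1.26, 1.44 and -0.55, and within slide 5 they were 0.77, 1.40 and -0.80.

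Cholesterol synthesis genes were lower for 13 of 18 and higher for 0 after cuprizone (14 adjusted over the list alone), with Hmgcs1, which makes HMG-CoA, at -1.73 ± 0.18, Idi1, an isomerase of the pathway, at -1.64 ± 0.20 and Msmo1, a sterol oxidase, at -1.45 ± 0.18. The call held with an estimated correlation (camera adjusted p = 1.75e-06 and 0.0324; median -0.72, -0.71 with slide as a block, -0.77 and -0.72 within slides). Progenitor transcription factors had 5 of 14 higher (5 adjusted over the list alone; camera adjusted p = 0.104), led by Sox4 at 2.91 ± 0.15. Hey1, a Notch target, was not well above background on any control array and at least 3.30-fold higher. Among 15 oligodendrocyte differentiation factors 1, Olig2, was higher at 1.04 ± 0.14 and 3 lower (4 adjusted over the list alone; camera adjusted p = 0.838). Of 11 cell cycle genes 3 were higher and 1, Cenpe, lower (4 adjusted over the list alone; camera adjusted p = 0.0604), with Ccnd1 at 3.39 ± 0.16 with 1 of 3 control arrays above background. Mki67 was not well above background on every array of either group and was not tested in set 2.

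Markers of microglia and macrophages rose after cuprizone: 11 of 14 were higher and 0 lower (12 adjusted over the list alone), with Itgam and Siglech saturated in both groups. Genes dim in control arrays were tested only where cuprizone arrays were bright, in this list and in every other list of this comparison. This favours a high share of tested members called higher. With no filter on dim probes 11 of 19 microglia and macrophage members were higher, 57.9% against 3.02% of other genes. The other lists of the report were not counted with no filter. Trem2, a lipid-sensing receptor, and Tyrobp, its signalling partner, were not well above background on any control array and were at least 7.98-fold and 7.86-fold higher after cuprizone (camera adjusted p = 1.14e-08; adjusted p = 0.122 with an estimated correlation; median 1.80, 1.80 with slide as a block, 1.76 and 1.99 within slides). Antigen presentation genes were higher for 8 of 9 and lower for 0 (8 adjusted over the list alone), with the class I molecule H2-D1 at 2.94 ± 0.20, the peptide transporter Tap2 at 2.10 ± 0.15 and B2m, the class I light chain, at 2.08 ± 0.19 (camera adjusted p = 2.94e-07; adjusted p = 0.107 with an estimated correlation; median 1.92, 1.96 with slide as a block, 1.62 and 2.02 within slides). Interferon response genes were higher for 11 of 15 (11 adjusted over the list alone), with Irf1, a transcription factor of the response, at 2.12 ± 0.37 and 2 of 3 control arrays above background (camera adjusted p = 7.84e-05; adjusted p = 0.122 with an estimated correlation; median 1.05, 1.08 with slide as a block, 1.02 and 1.12 within slides).

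Cytokine ligands had 3 of 10 higher and 2 lower (5 adjusted over the list alone; camera adjusted p = 0.944). Ccl4 and Ccl2, chemokines that attract monocytes, were not well above background on any control array and were at least 3.39-fold and 1.78-fold higher after cuprizone. Cntf, a ciliary neurotrophic factor, was at 1.63 ± 0.18 and Il33 at -1.90 ± 0.13. Il1b, which encodes interleukin 1 beta, was not well above background on any of the 18 arrays. Receptors and sensors had 6 of 15 higher and 2 lower (8 adjusted over the list alone; camera adjusted p = 0.0947), with Tnfrsf12a, the receptor of the cytokine TWEAK, at 3.25 ± 0.15 with 1 of 3 control arrays above background. Growth factor signalling had 8 of 15 higher and 2 lower (10 adjusted over the list alone), with Etv5, a transcription factor downstream of receptor tyrosine kinases, at 2.21 ± 0.30 (camera adjusted p = 0.00442; adjusted p = 0.150 with an estimated correlation; median 0.84, 0.84 with slide as a block, 0.74 and 0.86 within slides, 0.27 without control replicate 2, and 0.21 over the 12 members measured in both groups). In adhesion, guidance and migration 7 of 20 were higher and 2 lower (9 adjusted over the list alone), with Bcan at 3.38 ± 0.22 (camera adjusted p = 0.0459; adjusted p = 0.122 with an estimated correlation; median 0.16, 0.17 with slide as a block, 0.17 and 0.18 within slides). The adhesion call was lost without cuprizone replicates 2, 3 or 4 or control replicate 2 (adjusted p = 0.0760, 0.0560, 0.0590 and 0.0853). The median was 0.03 without control replicate 2, 0.29 without cuprizone replicate 1 and 0.26 over the 15 members measured in both groups. Members lower numbered 1 without cuprizone replicates 1, 2 or 4 or control replicate 3, and 0 without control replicate 1.

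Markers of the remaining cell types moved unevenly after cuprizone. Pericyte and fibroblast markers were higher for 3 of 4 (4 adjusted over the list alone), with Col1a2 at 1.24 ± 0.18 (camera adjusted p = 0.00271; adjusted p = 0.107 with an estimated correlation; median 1.06, 1.03 with slide as a block, 0.86 and 1.30 within slides, 0.53 without control replicate 3). Astrocyte markers were lower for 2 of 4, with the glutamate carrier Slc1a3 at -0.99 ± 0.14 (3 adjusted over the list alone; camera adjusted p = 0.513). Lymphocyte and granulocyte markers (1 of 4 higher), ependymal markers (1 of 3 lower), erythroid markers (0 of 3) and channels (2 of 7 higher, 2 lower) had camera adjusted p of 0.966, 0.234, 0.234 and 0.503. Adjusted over the list alone they held 1, 1, 0 and 5 calls. Only 2 neuron and 2 endothelial markers were tested, 1 of each higher, too few for a list test. Cell cycle passed without cuprizone replicates 1 or 4 or control replicate 2, receptors and sensors without cuprizone replicate 1, oxidative stress without control replicate 1 and respiratory chain without control replicate 2, at adjusted p from 0.00583 to 0.0441.

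**Figure D2:**
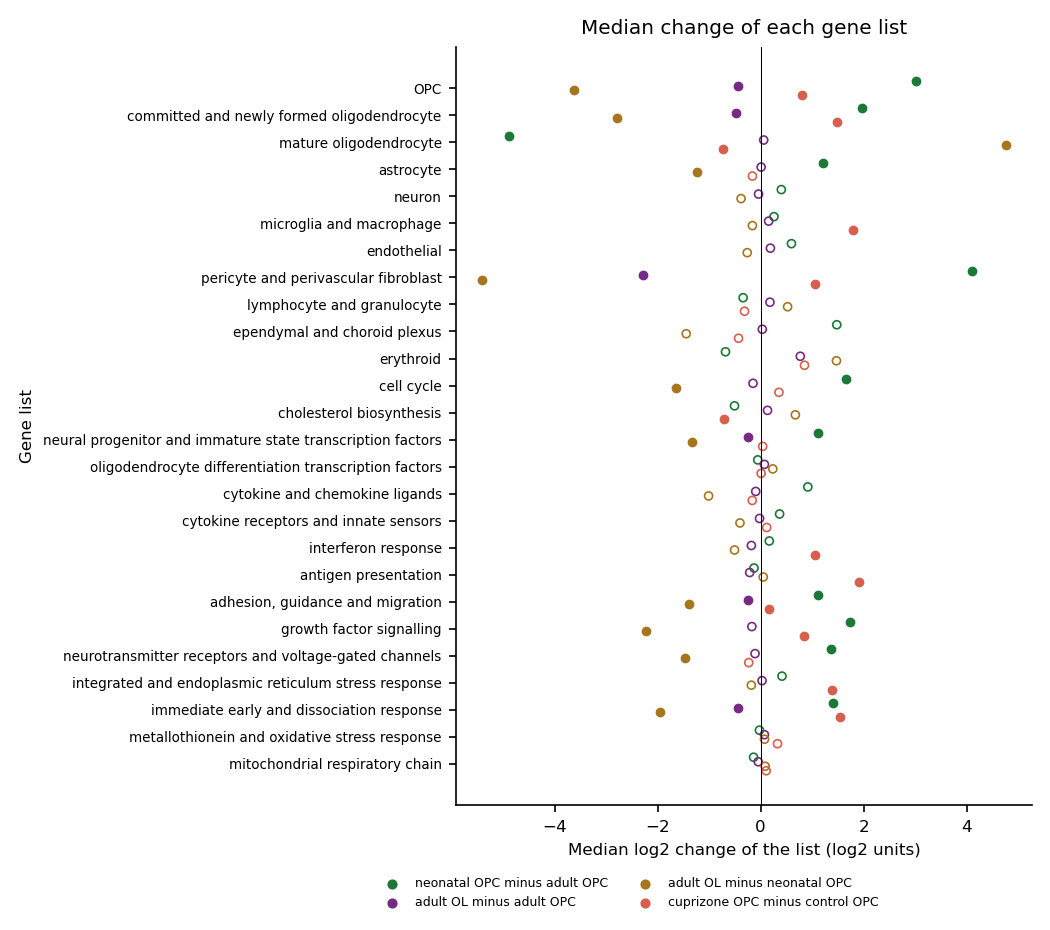
Median log2 change (x axis, log2 units) over the tested members of each fixed gene list (y axis) in 4 comparisons, drawn as points. Filled points passed camera at an adjusted p under 0.05 and open points did not. The mature oligodendrocyte list lay at -4.88 for neonatal minus adult OPC and at -0.74 for cuprizone minus control OPC.

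The cuprizone effect was then set against the neonatal effect, which shares no arrays with it. Across 8855 genes tested in both, the log2 change cuprizone minus control correlated with the log2 change neonatal minus adult at a Pearson r of 0.578 and a Spearman rho of 0.508, with a slope of 0.305. Genes are not independent replicates, so no p is given. With the cuprizone effect taken within slides 4 and 5, r was 0.557 and 0.539, and with both effects taken within slides it lay between 0.493 and 0.545. Genes higher in both numbered 653, against 209.07 for independent lists, and genes lower in both 845, against 363.99. Genes that moved in opposite directions numbered 33 and 88, against 214.44 and 354.87. Genes dim in control arrays were tested only where cuprizone arrays were bright, which favours shared rises. Of 2638 genes higher in neonatal OPCs 1487 were tested in both, and of 2889 lower 2524. The numbers for independent lists and the correlation do not allow for this choice of genes. With no filter on dim probes the correlation and the number of shared genes were lower, as given below. With normexp signals scaled to the 75th percentile instead of quantile normalized, 495 genes were higher and 1007 lower in both, and with the authors' processed values 331 and 284.

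By the smaller of the 2 changes, the largest shared by both comparisons were rises of Tagln2 (4.34 ± 0.30 in neonatal OPCs, 5.12 ± 0.13 after cuprizone), Marcks (4.81 ± 0.38 and 3.79 ± 0.25), Slc7a1 (3.77 ± 0.28 and 4.23 ± 0.15) and Vim, the intermediate filament vimentin of immature glia (4.31 ± 0.26 and 3.50 ± 0.21). Panx1, a membrane channel, was at 4.38 ± 0.29 in neonatal OPCs and at least 6.74-fold higher after cuprizone, with no control array above background. Shared falls were led by Jph4, which couples the plasma membrane to the endoplasmic reticulum (-4.38 ± 0.24 and -3.61 ± 0.25), Carns1 (-5.08 ± 0.27 and -3.15 ± 0.37), Ninj2 (-5.93 ± 0.25 and -2.65 ± 0.30), Sgk2 (-3.98 ± 0.49 and -2.62 ± 0.20) and Wfdc18 (-4.21 ± 0.25 and -2.52 ± 0.32).

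**Figure D3:**
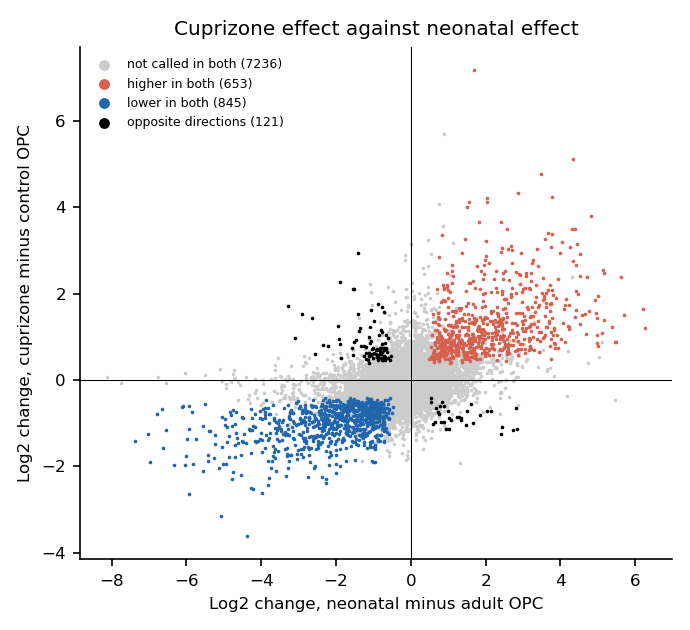
Log2 change cuprizone minus control OPC (y axis) against log2 change neonatal minus adult OPC (x axis) for 8855 genes. Each point is a gene, and colour marks the genes called in both, 653 higher in both, 845 lower in both and 121 in opposite directions. Pearson r across genes was 0.578.

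A neonatal score was made per array as the mean of 1000 genes at least 2-fold higher minus the mean of 1673 genes at least 2-fold lower in neonatal than in adult OPCs. These were the genes, of 1938 higher and 1750 lower, that passed the filter of set 2. Genes dim in control arrays passed it only where cuprizone arrays were bright, which favours a higher score after cuprizone. The permutation test kept this choice of genes and does not allow for it. The score was -0.21 ± 0.11 in cuprizone OPCs (SD, n = 4) and -1.55 ± 0.04 in control OPCs (SD, n = 3), a difference of 1.34 log2 units (exact two-sided permutation test, p = 0.0286, the smallest that 35 splits can give). The genes higher in neonatal OPCs rose by 0.82 after cuprizone and the genes lower changed by -0.52. Within slides 4 and 5 the difference was 1.34 and 1.32. It amounted to 32.8% of the distance between neonatal and adult OPCs in set 1, where the genes were chosen. A second score took the genes at least 2-fold higher, 22, or lower, 124, in adult OL than in adult OPC. It was 0.31 lower after cuprizone (difference -0.31; -0.05 ± 0.10, SD, n = 4, against 0.26 ± 0.14, n = 3; exact two-sided permutation test, p = 0.0286), with -0.11 and -0.45 within slides 4 and 5. The genes higher in OLs rose by 0.29 after cuprizone, against the direction of the score, and the genes lower in OLs by 0.60. This difference depended on single OL arrays, being 0.0001 with score genes chosen without adult OL replicate 1, and it lost its call with the authors' processed values (-0.16, exact permutation p = 0.286).

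**Figure D4:**
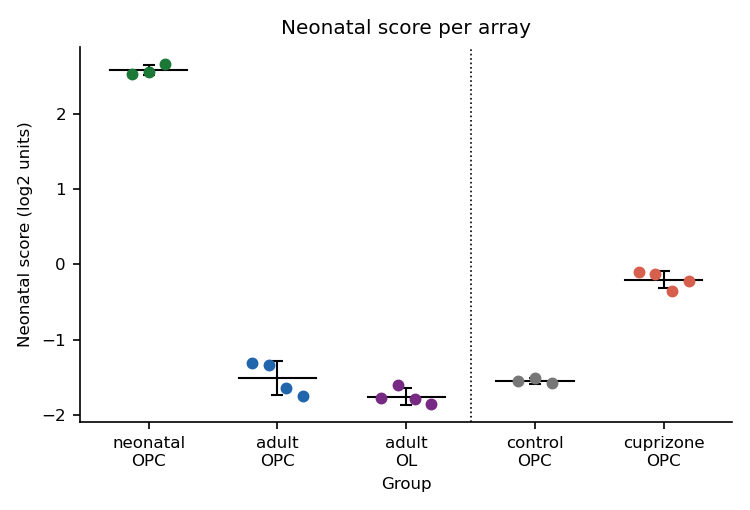
Neonatal score (y axis, log2 units) of each array, by group (x axis). Points are arrays, horizontal bars are group means and vertical bars are 1 SD. The score genes were chosen on the neonatal and adult OPC arrays left of the dotted line, among genes that passed the filter of the arrays right of it. Cuprizone arrays lay between -0.36 and -0.11 and control arrays between -1.58 and -1.50.

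The 2 groups of untreated adult OPCs, control OPC in set 2 and adult OPC in set 1, measure how far the sets differ with no treatment. Of 10501 genes 17 were lower and 0 higher in control OPC by limma, with 1685 at an unadjusted p under 0.05. With signals scaled to the 75th percentile the counts were 778 lower and 44 higher, and the median of all genes moved to -0.18. Each set held 1 of the groups, so set and group cannot be told apart. Lists lower in control OPC were committed and newly formed oligodendrocyte (0 of 12 called, camera adjusted p = 0.000255), pericyte and fibroblast (1 of 6, Anpep, adjusted p = 5.04e-05), antigen presentation (0 of 10, adjusted p = 0.00256), growth factor signalling (0 of 17, adjusted p = 0.00568), astrocyte (0 of 8, adjusted p = 0.0115) and interferon response (1 of 13, Ifi27l2a, adjusted p = 0.0267). With an estimated correlation their adjusted p was 0.348, and 0.429 for astrocytes. Adjusted over the list alone these lists held 2, 5, 0, 1, 2 and 4 calls, and the other 19 tested lists had camera adjusted p of 0.112 or more. The astrocyte call was lost without adult OPC replicate 2 (adjusted p = 0.0526; median -0.50 against -0.87). The interferon call was lost without adult OPC replicate 1 (adjusted p = 0.0504) and control replicate 1 (adjusted p = 0.115), its median was -0.35 without control replicates 1 or 2 against -0.61, and Ifi27l2a lost its call without any 1 array. Anpep lost its call without adult OPC replicate 2. The growth factor median was -0.57 without adult OPC replicate 4 and -0.59 without control replicate 2, against -0.36. Other lists passed at adjusted p from 0.00109 to 0.0473: cholesterol synthesis and immediate early without adult OPC replicate 2, neuron, lymphocyte, progenitor factors and adhesion without replicate 3, microglia, ependymal and erythroid without replicate 4, and channels without control replicate 2.

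The median change, mean change and camera direction of a list differed in sign for 12 of the list tests, none past the threshold. These were antigen presentation for neonatal minus adult OPC and for adult OL minus neonatal OPC, and mature oligodendrocyte, neuron, ependymal and stress lists for adult OL minus adult OPC. Neuron markers also differed for adult OL minus neonatal OPC, lymphocyte markers for cuprizone minus control, and oligodendrocyte factors and cytokine ligands for cuprizone minus control and for control minus adult OPC.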

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

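The tests of other splits of the arrays were planned. The further list of microglia genes and the other tests of explanations in this part were chosen after the result was seen. The gap between the most distant array of a group of 4 and its nearest neighbour, divided by the range of the group, exceeded the 95% critical value of Dixon for 13 of 206 groups of values tested, 6.31%, where chance gives about 1 in 20. Only values above background on all 4 arrays were tested, and groups of 3 were not.

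Adult OPC replicate 3 stood apart in 4 genes: Adamts4 (ratio 0.860; 14.21 against 15.58 log2 units, the mean of the other 3), Mbp (0.838; 13.86 against 14.47), Aspa (0.881; above the 14.54 of the others) and Ddit3 (0.892; 10.43 against 9.77). Single genes stood apart in other adult OPC arrays: Fcho1 in replicate 2 (0.928; 13.69 against 8.79), Fxyd6 in replicate 1 (0.853; 9.75 against 9.01) and Mcm6 in replicate 4 (0.872; 10.56 against 10.28). Among adult OL arrays, Cd44 was higher in replicate 1 (0.903; 11.06 against 9.77). Cuprizone replicate 2 had the highest signals of 3 microglia genes, Cd52 (0.917; 12.63 against 11.50), Ly86 (0.921; 12.58 against 11.92) and Trem2 (0.866; 13.21 against 12.56). Hey1 in cuprizone replicate 1 (0.849; 12.04 against 11.46) and Msmo1 in replicate 3 (0.852; 13.47 against 14.00) completed the set. The signal of Fcho1 in adult OPC replicate 2 was thus nearer to the OL mean of 15.53 than to the other adult OPC arrays.

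Chance is an unlikely source of the count of 5527 genes called between neonatal and adult OPCs, which no other split of the arrays reached (1 of 35 splits as large, the real one, and at most 2172 otherwise, with adult OPC replicates 1, 3 and 4 on one side). The same applies to the counts of 200 between adult OLs and adult OPCs (1 of 35; at most 2), 5944 between adult OLs and neonatal OPCs (1 of 35; at most 1563), and 2561 between cuprizone and control (1 of 35; at most 1). A share of 1 of 35 is the smallest that these splits can give, and the tests were not adjusted for their number. A positive correlation as large as 0.578 came from 1 of 35 splits too (at most 0.497 otherwise). By size alone 2 of 35 reached it, since the split with cuprizone replicate 3 beside the 3 controls gave -0.588. For the 17 genes between control and adult OPCs chance cannot be excluded, since 2 of 35 splits gave as many and the highest other gave 64, with control replicate 3 and adult OPC replicates 1 and 2 on one side. A count several times the real one points to a structure of these arrays other than their group, which was not tested.

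Mature oligodendrocyte transcripts in adult OPC arrays lay near their level in OL arrays. A minor share of oligodendrocyte RNA in the sort, with other cells free of these transcripts, would put OLs at least 2-fold higher. The median OL minus adult OPC difference was instead -0.071 over 15 markers measured in both groups, and -0.14, 0.28, -0.24 and -0.30 against the 4 adult OPC arrays. Markers counted as measured could still be saturated on some arrays of a group. Signals near saturation can compress a difference toward 0, which was not tested. Arrays measure shares of RNA and not of cells, so a minor share of oligodendrocytes holding more RNA per cell stays open. A sort made only of oligodendrocytes and cells like neonatal OPCs should hold no genes above both. Of 160 genes higher in adult OPCs than in OLs, 99, or 61.9%, were called higher in neonatal than in adult OPCs, as such a sort would give. Another 32 were not called between neonatal and adult OPCs. The other 29, 18.1%, were called higher in adult than in neonatal OPCs as well, Smco3 (-4.54 in OLs and -4.49 in neonatal OPCs) among them. Of all 12032 genes tested, 2889 were called higher in adult than in neonatal OPCs. Both comparisons share the adult OPC arrays. Genes above both groups were also picked on some arrays and measured on the others. Their median excess ran from -0.35 to 1.31 over 108 ways to part the arrays, with 8 at or below 0. A sort made only of these 2 kinds of cell therefore stays open. Adult precursors that themselves carry these transcripts, the difference of age that the design names, also stay open, untested.

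Microglia and macrophage markers rose after cuprizone. Microglia or macrophages in the cuprizone sort are a candidate source: of 20 further microglia genes, 4 of which also stand on the lists of the report, 5 were higher with no filter on dim probes, 25.0% against 3.02% of other genes, and 6 were above background on no cuprizone array, so the test does not decide (the count with the filter, 5 of the 6 that passed it, was set aside because genes dim in control arrays pass only where cuprizone arrays are bright). The 5 were Ly86, at least 5.13-fold (mean log2 signal 12.08), Cd52, at least 4.17-fold (11.78), Coro1a, at least 1.85-fold, Selplg, at least 1.74-fold, and Cyba at 1.55, while Arhgdib was at 0.13, and Cyba and Arhgdib were above background in control arrays too. A lower share of the main cell type alone would raise other markers alike. List medians over members not saturated in both groups, averaged over the 4 arrays, moved apart: 2.14 ± 0.28 (SD, n = 4) for microglia, 1.15 ± 0.14 for pericytes and fibroblasts, 0.80 ± 0.84 for erythroid cells, -0.16 ± 0.15 for astrocytes (4 markers tested), -0.24 ± 0.59 for lymphocytes and granulocytes and -0.43 ± 0.28 for ependyma. These members had passed the filter, and with no filter the median of the microglia list of the report was 1.61. The other lists rest on few markers each and were not run with no filter, so the medians do not settle this. The sort marker was not given in the sources used here, so it is open whether it would remove such cells, and expression by the precursors themselves was not tested.

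The cuprizone effect resembled the neonatal effect. The filter on dim probes favours shared rises, as stated above, and how much of the resemblance it gave was not tested. A fall of all oligodendrocyte RNA by a common factor would give equal changes where signals are proportional to RNA. Of 13 mature markers, 9 departed from their median change of -1.26 by over 2 SE, from Ninj2 at -2.65 to Gjb1 at -0.19. Signals near saturation and the background offset can compress changes unequally, which was not tested, so a common factor is not excluded. A difference between slides was argued against by a correlation of 0.493 or more with both effects taken within single slides. A change of the precursors themselves under cuprizone, the treatment that the design names, and an altered mix of cells in the sort stay open, untested.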

How the results depend on the processing

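The plain subtraction of background and, for the gene lists, the slide block and 75th percentile scaling were tests chosen after the result was seen, and the other settings were planned. The correlation, the neonatal score and the distance kept their direction under each alternative run. Fewer genes were tested when every array had to be above background, and the counts of called genes were lower: 3302 for neonatal minus adult OPC, 83 for adult OL minus adult OPC, 3486 for adult OL minus neonatal OPC and 0 for control minus adult OPC (limma; 1685 at an unadjusted p under 0.05 with the filter of the report). With no filter the cuprizone count was 1158, the control minus adult count 11, the correlation 0.456 and the shared genes 791. With the authors' processed values the cuprizone count was 957, the control minus adult count 104 with the median of all genes at -0.15, the shared genes 615 and the oligodendrocyte score -0.16 (exact permutation p = 0.286). The score was -0.24 (exact permutation p = 0.114) with every array above background. The cause was not tested for the authors' values.

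Adult OL minus adult OPC gave 526 genes with array weights, 310 with only the 2 groups compared, 119 with slide as a block and 113 with plain subtraction of background. Control minus adult OPC gave 822 with 75th percentile scaling, where the median of all genes lay at -0.18 and the median of the mature oligodendrocyte list turned to -1.10. It gave 106 with array weights, 79 with all 5 groups in 1 fit, 70 with slide as a random block, 26 for single probes and 2 with replicate number as a block. With only genes called in the neonatal comparison the correlation was 0.683. The cause was not tested for these. In cuprizone minus control, 75th percentile scaling moved the median of all genes to -0.10.

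Leaving out single arrays gave 112 to 182 genes for adult OL minus adult OPC, with 113 without adult OPC replicate 1, 119 without replicate 3, and 120, 118 and 112 without adult OL replicates 1, 3 and 4. It gave 0 to 18 for control minus adult OPC: 2, 0 and 2 without adult OPC replicates 1, 2 and 3, and 4 and 11 without control replicates 2 and 3. The neonatal score difference ran from 1.26 to 1.40 and the oligodendrocyte score difference from -0.38 to 0.0001, the latter without adult OL replicate 1. Without adult OL replicate 4 it was -0.09 (exact permutation p = 0.400), and without OL replicate 2 or adult OPC replicate 1 the exact permutation p was 0.0571. Leaving out an array of set 2 leaves a smallest exact permutation p of 0.1 or 0.0667, so neither score could pass there. The counts ran from 4934 to 5842 for neonatal minus adult, from 5265 to 6357 for adult OL minus neonatal and from 1975 to 2213 for cuprizone, with 1189 to 1508 shared genes, a correlation of 0.547 to 0.587 and a distance of 0.813 to 0.907.

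Arrays of the same replicate number had a mean residual correlation of -0.05 in set 1 and 0.04 in set 2. Pairs of other numbers had 0.02 and -0.02. Pairing by number was thus not apparent, but with few pairs it is not excluded. As a block replicate numbers gave 4839, 154, 5252 and 2036 genes for the 4 main comparisons, a correlation of 0.569 and 1201 shared genes. Across settings the named genes lost their call in 44 of 1855 values for neonatal minus adult, 71 of 699 for adult OL minus adult OPC, 2 of 217 for adult OL minus neonatal and 70 of 1611 for cuprizone, with 0 reversed. With an estimated correlation 10, 5, 10, 9 and 6 list calls were lost in these comparisons and, last, in control minus adult OPC. With fry, in the same order, 0, 4, 0, 0 and 6 were lost and 4, 0, 4, 7 and 0 gained. Scan date did not vary within a set and was not run as a block. Signal over background limited which genes were tested in set 2, where 32.6% to 44.5% of probes passed, and several changes could be given as bounds only.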

Other observations

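The results on genes in opposite directions below were chosen after the result was seen, and no test of an explanation was planned for them. A small group of genes moved in opposite directions in the neonatal and cuprizone comparisons, 33 higher in neonatal OPCs and lower after cuprizone and 88 the reverse, against 653 higher and 845 lower in both. Ddit3, a transcription factor of the integrated stress response, was at -1.88 ± 0.31 in neonatal against adult OPCs and at 2.27 ± 0.21 after cuprizone, and Mthfd2, of mitochondrial folate metabolism, at -2.65 ± 0.28 and 1.44 ± 0.17. The complement component C4b was at -1.53 ± 0.45 and 2.11 ± 0.18, and H2-D1 at -1.42 ± 0.44, a call lost without adult OPC replicate 1 or neonatal replicate 3, and 2.94 ± 0.20. Arap2, a regulator of small GTPases, was at -3.29 ± 0.53 and 1.71 ± 0.15. Pou3f1, a transcription factor of myelinating glia, was at -1.96 ± 0.22 and 1.24 ± 0.21.

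In the other direction, Cenpe, a kinetochore motor, was at 2.73 ± 0.20 in neonatal OPCs and at -1.17 ± 0.38 after cuprizone, and Col6a3, a collagen, at 2.85 ± 0.20 and -1.14 ± 0.20. Slc13a3, a carrier of dicarboxylates, was at 2.42 ± 0.25 in neonatal OPCs and at least 1.86-fold lower after cuprizone. Across the 8855 genes tested in both, the slope of the cuprizone on the neonatal effect was 0.305.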
